A study of Homo sapiens with 3 samples.

How the data were processed

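Total RNA from ovarian cancer stem cells derived from A2780, a human ovarian carcinoma line, was measured on single-colour Agilent whole-genome expression arrays with Cy3-labelled RNA. There were 3 arrays and 3 groups: unstimulated cells, cells given the cytokine interleukin 17A (IL17A) for 4 h, and cells given IL17A for 6 h. Each group had 1 array, so no difference has a replicate check, no test between groups was possible and no p-value is given. The number of arrays limits the precision of every value. How long the unstimulated cells were kept beside the treated ones is not given in the sources used here.

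The deposited scanner files hold linear spot intensity values, and per the file headers they were extracted with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 10.5.1.1. Background-subtracted intensity (the processed signal) was the starting point, as the authors deposited it, with no scaling between arrays. Per the file headers all 3 arrays shared 1 scan, so no scan batch separates the groups. The authors also deposited a value table of 11311 probes on a log2 scale, whose scale and centring are not given in the sources used here. Set against the scanner values, each of its columns correlated with log2 processed signal above 0.9999 across probes and lay a constant below it (-6.07 for unstimulated, -7.06 for 4 h and -6.08 for 6 h). That constant lay near each array's median log2 signal of 6.01, 7.01 and 6.02, the genes were not centred, and why the constants differ slightly from those medians stays unknown. The medians of its columns were 1.07, 1.08 and 1.00, and the direction of its values followed the scanner values.

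Each array held 45015 spots, of which 1639 were control spots and were left out, leaving 43376 spots of 41000 probes. Log2 processed signal was taken relative to the 75th percentile of its array, spots of one probe were averaged on that scale, and a gene was represented by its brightest probe over the 3 arrays. Probes of one gene often disagreed. Among genes with several measured probes, of which at least 1 was 2-fold apart, probes had opposite signs at 4 h in 45 of 115 genes of the stricter set described next and 935 of 1710 of the wider set, and at 6 h in 13 of 29 and 88 of 161. The text gives further probes of a named gene where they were well above background and differed in direction, and gives no difference for probes that were not. Probes were named by matching their RefSeq accession, without version, to a gene table of assembly GRCh38.p14. This named 26877 probes for 18016 genes and left 14123 probes unnamed. The genome build in the file headers is hg19, so no coordinates are printed.

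A gene entered a comparison when its probe was well above background, by the scanner software's own call, on both arrays and carried no scanner outlier flag on either (the stricter set). The outlier flag lay on 29.0%, 34.5% and 27.7% of spots on the unstimulated, 4 h and 6 h arrays. Among the brightest 30% of spots it lay on 82.9%, 90.0% and 81.8%, and among the dimmest 50% on 0.120%, 0.129% and 0.184%, so that the stricter set holds few bright genes. Counts and gene lists are therefore also given with the outlier flag ignored (the wider set). Genes well above background on all 3 arrays numbered 2792 in the stricter and 11708 in the wider set.

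A difference of at least 2-fold was counted as higher or lower. A gene that was well above background on 1 array of a pair has only a bound. It is written as at least N-fold, from its level on the brighter array against the higher of its own dim level and the lowest level among probes well above background on the dimmer array. Gene lists, 30 in number, were fixed before the data were examined, and 1 list of liver transcripts was added afterwards. For each list with at least 5 measured members the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn to match its members' mean level in 10 bins. A list is said to stand apart below the 2.5 or above the 97.5 percentile, which describes these arrays only. About 5 in 100 lists of genes drawn at random would do so. Members of one list can vary together between arrays, so this is no rate of false calls for the lists used here. Random lists were not matched on gene length. In an alternative chosen after seeing the data, the median difference of each of 20 bins of genomic gene length was removed before lists of the wider set were placed.

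The genes named were fixed by a rule before the data were examined. For each comparison against unstimulated cells the rule took the 10 highest and 10 lowest among genes in the stricter set on all 3 arrays, above the lowest 25% of mean level, whose probes in that set had the same direction. It took the 5 highest and 5 lowest for 6 h against 4 h, and the same numbers for genes at least 2-fold apart in the same direction at both times. It also took 3 bounds per direction, the 4 members of each list with the greatest absolute difference, and a fixed set of IL17A, receptor and stem cell genes. Genes outside this rule are marked as chosen after their values were seen.

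Both comparisons against unstimulated cells share that 1 array. The correlation of their differences was set beside a simulation of unchanged arrays with a log2 spread of 0.144, the standard deviation of repeated spots averaged over arrays. The number of genes shared by both was set beside the number that independent lists would share. The control could not be split.

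Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for quantile, cyclic loess and normexp (offset 50) alternatives. The procedure was tested on simulated data for the 6 h comparison over 4044 genes, with 200 genes given known differences on arrays of that spread. A 2-fold threshold recovered 2.0% of genes with a true 1.5-fold difference, 56.0% at 2-fold, 98.0% at 3-fold and 100.0% at 4-fold. Among 200 simulated lists of 15 genes, 4.0% of unshifted lists and 99.5% of lists shifted by 0.3 stood apart. That spread is the noise of repeated spots within an array and leaves out differences between cultures, extractions and labellings, so these figures, and the simulated correlation and covariance, give no rate of false calls for the arrays compared here.

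The alternatives tried were a 1.5-fold threshold, scaling by the array median, quantile and cyclic loess normalization, the authors' value table, no filter and a stricter filter on dim probes, the outlier flag ignored, other rules for several probes per gene, and normexp background correction.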

Results

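Gene expression was measured in A2780-derived ovarian cancer stem cells, grown without serum with fibroblast and epidermal growth factors, on 3 single-colour Agilent arrays of 1 sample each: unstimulated, IL17A for 4 h and IL17A for 6 h. IL17A is a proinflammatory cytokine that acts through the receptor chains IL17RA and IL17RC. The design asks which genes differ in these cells after 4 h and 6 h of IL17A. The 75th percentile of spot signal was 1114 on the unstimulated, 2005 on the 4 h and 1040 on the 6 h array, and 54.0%, 59.8% and 60.2% of spots were well above background. Repeated spots of one probe had a standard deviation of 0.165, 0.133 and 0.134 log2 units. Values are log2 differences after each array was scaled to its own 75th percentile. With 1 array per group no difference has a replicate check.

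The genes most often used to read an IL17A response were largely below measurement. CXCL8, CXCL2, CCL20 and IL6, secreted chemokines and a cytokine of epithelial inflammation, LCN2, an antimicrobial lipocalin, and PROM1, a stem cell surface marker, were not well above background on any array. CXCL1 was well above background on the 6 h array alone, at least 1.39-fold above the 4 h array and with no bound against the unstimulated array. NFKBIZ, a nuclear cofactor of IL17A-driven transcription, was higher by 0.86 at 4 h and lower (-0.15) at 6 h. TNFAIP3, a deubiquitinase that dampens NF-kB signalling, was higher by 1.05 at 4 h and by 0.34 at 6 h. The NF-kB inhibitor NFKBIA differed by -0.64 and -0.07, and the ribonuclease ZC3H12A by -0.16 and 0.12. For the receptor, IL17RA was 2.14-fold higher at 4 h and differed by 0.13 at 6 h, its adaptor TRAF3IP2 differed by 0.71 and -0.32, and IL17RC was well above background on the 4 h array alone, at least 1.12-fold above unstimulated. NFKBIZ, TNFAIP3 and IL17RA carried the scanner's outlier flag on the 4 h array. NFKBIA and ZC3H12A carried it on the unstimulated array, the 4 h array or both. The 4 h values of these genes therefore belong to the wider set.

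Stem cell genes of the fixed set that were measured on all 3 arrays lay below 0 at 4 h, where the median of all genes lay below 0 as well. NANOG, a pluripotency factor, differed by -1.16 at 4 h and -0.03 at 6 h, and ABCG2, a drug efflux pump, by -0.74 and -0.03. ALDH1A1, a retinal dehydrogenase used as a stem cell marker, differed by -0.37 and 0.26, and POU5F1, another pluripotency factor, by -0.14 and 0.27. SOX2, a partner of POU5F1, was not well above background on the 4 h array, where the unstimulated array was at least 2.45-fold and the 6 h array at least 3.37-fold higher. NANOG, ABCG2 and ALDH1A1 carried the outlier flag on all 3 arrays.

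**Figure D1:**
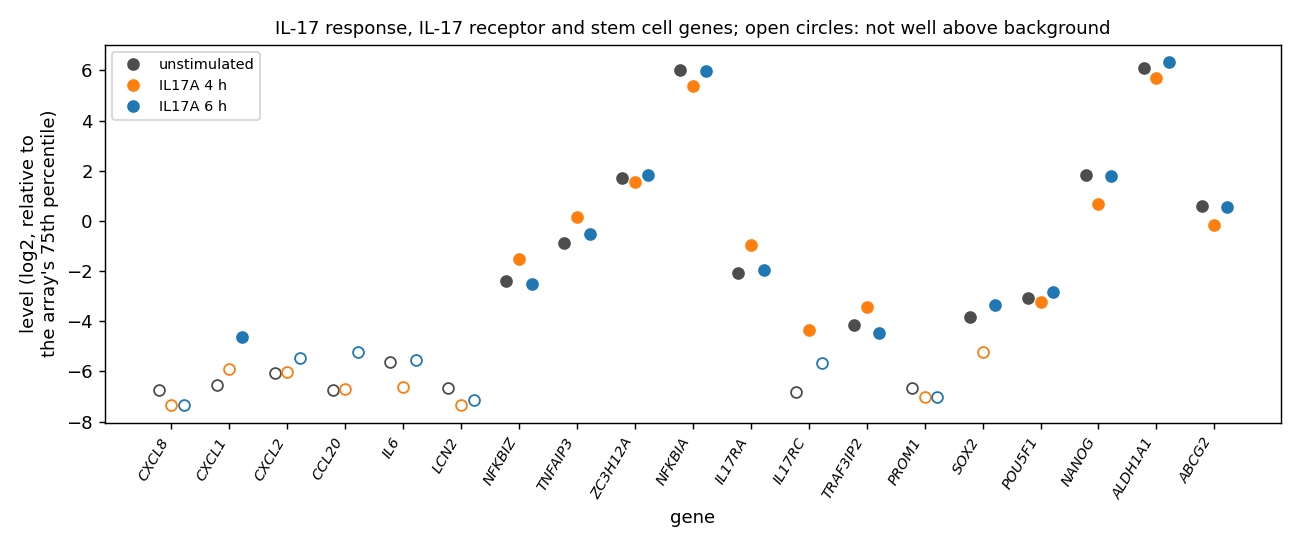
Levels of 19 IL17A, receptor and stem cell genes on the 3 arrays, as log2 signal relative to each array's 75th percentile on the vertical axis, with open symbols where the probe was not well above background. CXCL8, CXCL2, CCL20, IL6, LCN2 and PROM1 are open on all 3 arrays, while NANOG differed by -1.16 between the 4 h and the unstimulated array.

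Genes were ranked among those of the stricter set on all 3 arrays, above the lowest 25% of level, whose probes in that set had one direction. Within this ranking IFI35, SIRT6 and PPP1R15A were among the highest at 4 h, and CYBA, SERPINA1 and A2M were the lowest. IFI35, an interferon-induced protein, was 9.35-fold higher (log2 3.23), SIRT6, a chromatin deacetylase, 7.25-fold, and PPP1R15A, the stress-induced phosphatase subunit that restores translation, 6.30-fold. ELK1, an ETS factor that acts with serum response factor, was 5.74-fold higher, and CARS1, a cysteinyl-tRNA synthetase, 5.38-fold. CYBA, the membrane subunit of the NADPH oxidases, was the lowest at -5.27, with a signal of 2143 on the unstimulated and 99.9 on the 4 h array. SERPINA1 (antitrypsin) was at -3.48, the protease inhibitor A2M at -3.42, transferrin (TF) at -3.02 and fetuin (AHSG) at -2.51. Of 2913 genes in the stricter set, 236 were at least 2-fold higher and 348 lower; in the wider set of 11748 genes these counts were 1412 and 1497.

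The split depended on scaling. The median of all genes at 4 h was -0.42 in the stricter and -0.39 in the wider set, and counted about that median the stricter set held 421 higher and 91 lower genes, which moved the share of higher among 2-fold genes from 40.4% to 82.2%. Relative to the median, IFI35 stood at 3.64, PPP1R15A at 3.07, NFKBIZ at 1.25, TNFAIP3 at 1.44, IL17RA at 1.48, NANOG at -0.77, SERPINA1 at -3.06 and CYBA at -4.85. The other genes among the 10 highest of the ranking were MARK2 (2.71), a microtubule-affinity kinase, LRRC41 (2.56), MFSD2A (2.41), a lysolipid transporter, SYTL1 (2.37) and FAM118A (2.33). The others among the 10 lowest were TNNI2 (-2.86), a fast skeletal troponin, ZNF2 (-2.82), LYNX1 (-2.78), a modulator of nicotinic receptors, LRRC61 (-2.57) and HBA2 (-2.45), an alpha globin whose sequence is shared with HBA1. A further MARK2 probe went the other way, well above background on the unstimulated but not on the 4 h array. Of the further ZNF2 probes 1 was at 0.15 and another was well above background on the 4 h array alone.

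Bounds added GHRH, the hypothalamic growth hormone releasing factor, at least 11.8-fold lower, with GARIN5B at least 14.9-fold and MORC1 at least 8.53-fold lower at 4 h. RHBG, an ammonium transporter, was at least 5.62-fold higher, ZNF765 at least 6.61-fold, and ANXA2P1, a pseudogene of annexin A2 whose probe can take up transcripts of its parent gene, at least 8.57-fold.

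**Figure D2:**
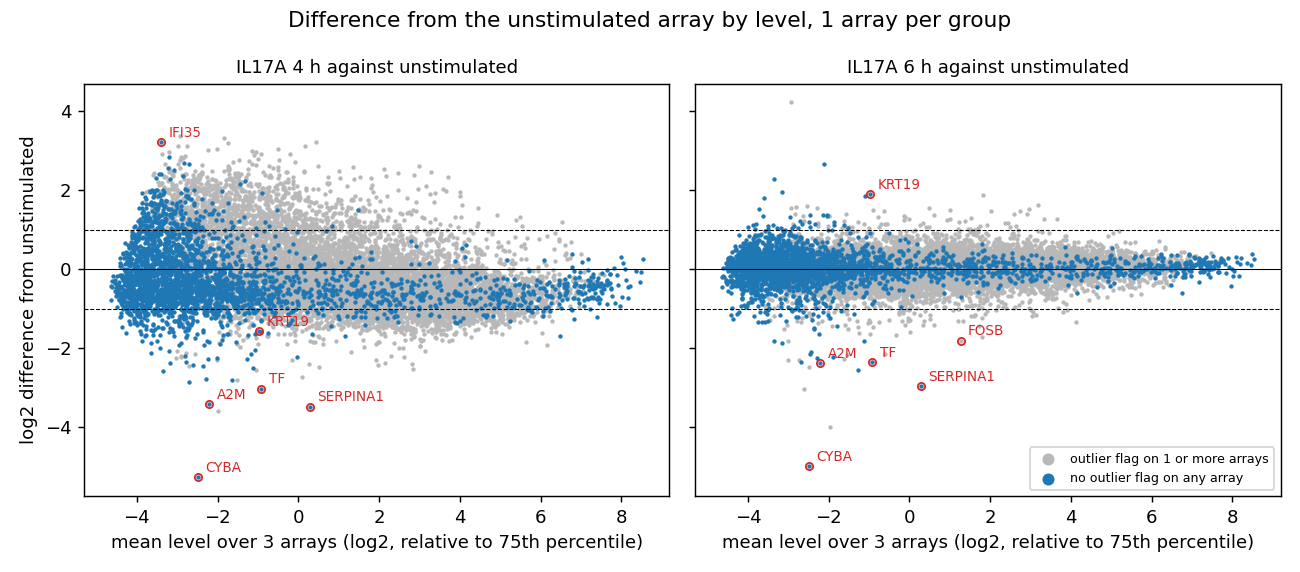
Log2 difference from the unstimulated array (vertical axis) against mean log2 level relative to the 75th percentile (horizontal axis) at 4 h and 6 h, 1 point per gene well above background on all 3 arrays, blue without and grey with a scanner outlier flag on at least 1 array. The standard deviation of the 2792 blue genes was 0.78 at 4 h and 0.41 at 6 h, and CYBA lay lowest among the blue points in both (-5.27 and -4.99).

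Among gene lists at 4 h, the IL17A targets measured in the wider set (12 of 40 on the array) had a median of 0.20 against -0.35 in matched random lists (percentile 96.0), short of standing apart; with the median over a gene's probes in the stricter set, the sign turned (-0.11, 5 genes). Of these, 1 was at least 2-fold higher and 0 lower, with complement C3 at 0.86, TNF at 0.51 and MMP9 at -0.77. NF-kB targets (27 measured, 4 higher and 1 lower) had a median of -0.12 against -0.39 (percentile 93.0); RELA, the NF-kB subunit itself, was at 1.73, BIRC3 at -1.09 and CYLD at 1.14, although a dimmer CYLD probe without the outlier flag was at -0.44. With quantile normalization of the wider set, an alternative chosen after seeing the data, the NF-kB median was 0.19 and its percentile 98.1; with a trend on gene length removed instead, its percentile was 87.5. Stem cell genes (17 measured, 2 higher and 4 lower) had a median of -0.47 against -0.39 (percentile 35.1), with NES, a neural progenitor filament, at 1.58, the DNA methyltransferase DNMT3B at -1.40, the receptor KIT at -1.37 and BMI1, a Polycomb subunit, at -1.23 with its brighter and 1.67 with its dimmer probe.

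Of 31 lists tested at 4 h in the wider set, 9 stood apart above their matched lists and 4 below. Ribosomal protein genes (60 measured, 4 higher and 0 lower) had a median of -0.12 against -0.63, and oxidative phosphorylation genes (54, 9 higher and 1 lower) -0.22 against -0.60, with the ATP synthase subunit ATP5F1B at 2.39 and cytochrome CYC1 at 2.17. The unfolded protein and ATF4 list (30, 4 higher and 2 lower) had -0.23 against -0.56, with DDIT3, a stress-induced transcription factor, at 2.30, and SESN2 at 2.20. For the chaperone HSPA5, the probe used was at 1.91 and carried the outlier flag on all 3 arrays, while a probe of similar brightness without the flag was at -0.72. Heat shock genes (18, 4 higher and 1 lower) had -0.10 against -0.50, with AHSA1 at 2.52 and HSP90AB1 at 2.37. Hypoxia and glycolysis genes (32, 4 higher and 2 lower) had -0.23 against -0.57. Among them GAPDH was at 2.04 and ENO1 at 1.98, while BNIP3 was at -0.94 and ALDOA at -0.50. NRF2 and metallothionein genes (23) had -0.24 against -0.56, and housekeeping genes (19) -0.03 against -0.59. These medians lay below 0 on the 75th-percentile scale and above 0 with quantile normalization (0.09 for ribosomal and 0.11 for unfolded protein genes), so that their signs rest on the scaling. Histone genes (22, 4 higher and 1 lower) had 0.42 against -0.23, with H2BC5 at 1.82, and G2/M genes (26) -0.22 against -0.51, the latter not apart with quantile normalization (percentile 87.4). Longer genes were lower at 4 h (Spearman correlation -0.187 with genomic gene length), and the genes of the ribosomal (median length 4.75 kb), oxidative phosphorylation (10.8 kb) and histone (0.493 kb) lists are short beside a median of 29.3 kb. With the length trend removed, an alternative chosen after seeing the data, G2/M and NRF2 genes did not stand apart (percentiles 81.9 and 95.2). The other 7 lists above still did, with 97.7 for heat shock and 97.9 for histone genes. Lists of the wider set rest on the brightest probe of each gene, and other rules for several probes were not tried there. In that set probes had opposite signs at 4 h in 935 of 1710 genes with several measured probes and a 2-fold probe. How far these list medians depend on the choice of probe was not tested.

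Below their matched lists at 4 h lay growth factor and receptor genes (20, 1 higher and 5 lower), with a median of -0.66 against -0.33, FGF2 at -1.50 and the EGFR ligand EREG at -1.42. The KIT ligand KITLG was at -1.52 with its brightest probe, which carried the outlier flag, and at 0.00 with a dimmer probe without it, and a further probe was well above background on the 4 h array alone. Notch, Wnt and Hedgehog genes (20, 3 higher and 5 lower) had -0.65 against -0.28 and leukocyte genes (9, 0 higher and 0 lower) -0.70 against -0.04; neither stood apart with quantile normalization (percentiles 9.23 and 2.90). The liver list, added after seeing the data, had a median of -0.78 against -0.14 over 16 genes. With the length trend removed, growth factor genes did not stand apart (percentile 5.69) and the other 3 lists did. In the stricter set 13 lists could be tested at 4 h, and ribosomal, housekeeping and liver genes stood apart. There oxidative phosphorylation genes (9) had -0.60 against -0.58, hypoxia and glycolysis genes (7) -0.50 against -0.56 and histone genes (5) -0.41 against -0.46, at percentiles 45.9, 60.1 and 55.5. Growth factor (9) and leukocyte genes (8) were at 33.3 and 18.3.

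**Figure D3:**
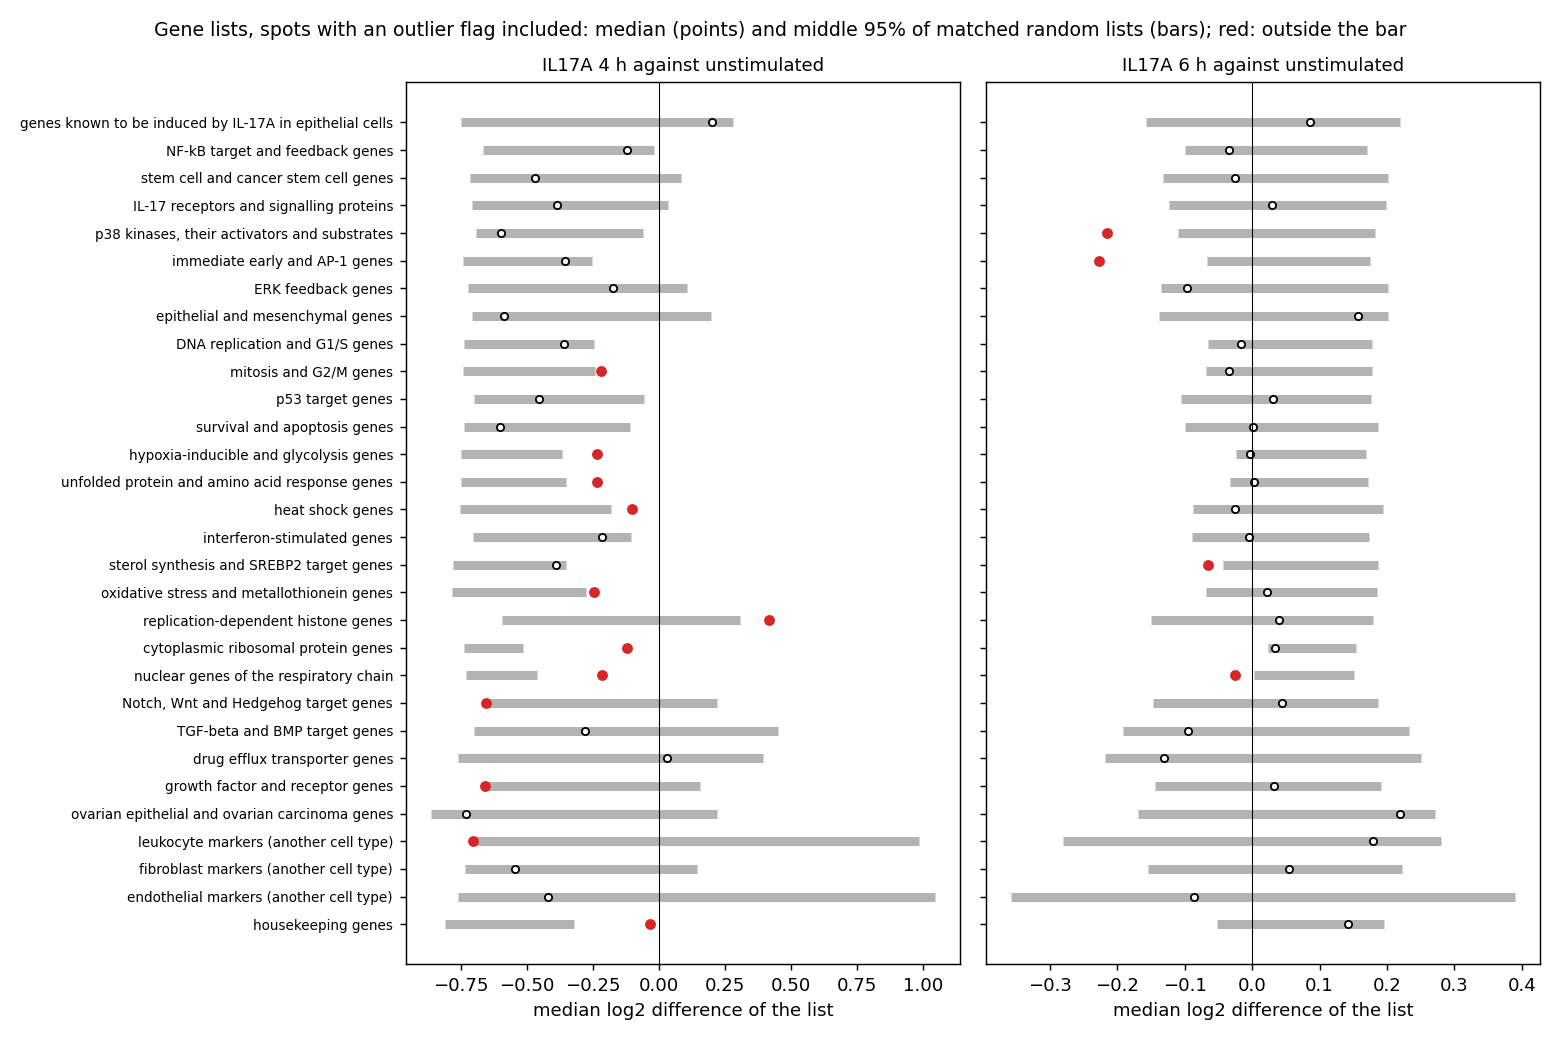
Median log2 difference from the unstimulated array of the 30 gene lists fixed before the data were examined, in the wider set at 4 h and 6 h (horizontal axis), with bars for the middle 95% of level-matched random lists and red points outside them. Ribosomal genes lay at -0.12 against -0.63 in matched lists at 4 h, and immediate early genes at -0.23 against 0.05 at 6 h; with quantile normalization the ribosomal median is above 0 (0.09).

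At 6 h fewer genes differed by 2-fold than at 4 h, and CYBA and SERPINA1 were again the lowest of the ranking, which leaves out genes with the outlier flag on any array. CYBA was at -4.99 (signal 63.1), SERPINA1 at -2.97, A2M at -2.38 and TF at -2.36, while ALDH4A1, a mitochondrial enzyme of proline breakdown, was at -2.55. MAPKAPK2, a kinase downstream of p38, was 4.70-fold lower (-2.23), SNCB, beta-synuclein, 4.42-fold and ELP5, a subunit of the Elongator complex, 4.29-fold. FAM43B was 6.32-fold higher, NSG1, a neuronal endosomal protein, 4.89-fold, RNASE1, a secreted ribonuclease, 3.87-fold and KRT19, a keratin of simple epithelia, 3.73-fold. In the stricter set of 4044 genes 45 were at least 2-fold higher and 82 lower, and in the wider set of 11832 genes 106 and 143, with medians of all genes of 0.01 and 0.04.

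Among the 10 highest of the ranking at 6 h were also LBX2-AS1 (1.86), SLC17A7, a vesicular glutamate transporter (1.39), C21orf58 (1.38), LCE3E, a protein of the cornified envelope (1.37), APOA2, an apolipoprotein of high-density lipoprotein (1.34), and NPY1R, a neuropeptide Y receptor (1.33). TNNI2 (-2.34) and LYNX1 (-2.24) completed the 10 lowest. Probes disagreed for ALDH4A1, with a second probe at -0.28 and a further one well above background on the 6 h array alone, and for AHSG, with probes at -1.81 and 1.19. A second TF probe was well above background on the 6 h array alone. By bounds, GARIN5B was at least 14.9-fold, GHRH at least 11.7-fold and LINC01366 at least 6.55-fold lower, and TCEAL7 at least 5.63-fold, HAP1, a huntingtin-associated protein, at least 5.01-fold and the lipocalin LCN15 at least 4.75-fold higher.

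Immediate early genes as a list lay below their matched genes at 6 h. Their median over 28 measured genes of the wider set was -0.23 against 0.05 in matched lists (percentile 0.00), with 0 higher and 3 lower by 2-fold: FOSB at -1.81, FOS at -1.43 and JUN at -1.11, all subunits of the AP-1 transcription factor. The p38 pathway list (22 genes, 0 higher and 1 lower) had a median of -0.22 against 0.04 (percentile 0.06), with MAPKAPK2 at -2.23, the phosphatase DUSP1 at -0.99 and the kinase MAP3K5 at 0.60. Cholesterol synthesis genes (24) had -0.07 against 0.07 (percentile 1.05), and oxidative phosphorylation genes (54) had -0.03 against 0.08 (percentile 0.16). These were the 4 lists of 31 that stood apart at 6 h in the wider set; with the gene-length trend removed, oxidative phosphorylation genes did not (percentile 2.73). In the stricter set 26 could be tested, and the epithelial-mesenchymal list alone stood apart (9 genes, 0.22 against 0.02), with a percentile of 97.51 that fell short of the limit in another draw of random lists, with KRT19 at 1.90 and SPARC, a matrix protein, at 0.51; in the wider set its percentile was 92.2. In the stricter set the p38 list (7 genes) was at percentile 9.28 and oxidative phosphorylation genes (11) at 44.0, while immediate early (3) and cholesterol genes (3) were too few.

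The lists closest to the treatment did not stand apart at 6 h. IL17A targets (15 measured in the wider set) had a median of 0.09 against 0.04 (percentile 68.5), NF-kB targets (28) -0.03 against 0.04 (percentile 16.5) and stem cell genes (19) -0.03 against 0.04 (percentile 22.6). Among their members TNF was at 0.63, TRAF1, a signalling adaptor, at 0.59, C3 at -0.67, MMP1, a collagenase, at -0.70 and the chemokine CXCL10 at -0.45.

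Across both times, 28 genes of the stricter set were at least 2-fold lower on both treated arrays, among them CYBA, SERPINA1, A2M, TF and TNNI2, where independent lists (319 and 47 calls among 2792 genes) would share 5.37. Genes at least 2-fold higher at both times were 5, against 2.78 for independent lists: SLC17A7 (1.41 and 1.39), GIPC1, a PDZ adaptor protein (1.33 and 1.11), PRDM16-DT (1.24 and 1.07), DCDC2, a doublecortin-domain protein (2.07-fold and 2.15-fold), and RNASE1 (1.00 and 1.95). Both comparisons share the unstimulated array, which could not be split, so part of the excess may come from that array. The correlation of the differences across genes, which are not independent replicates, was 0.16 with a covariance of 0.05. In the wider set it was -0.09 with a covariance of -0.03. Simulated unchanged arrays gave 0.51 and 0.02. Equal noise on every simulated array set that correlation, whereas the measured differences had unequal standard deviations (0.78 and 0.41). The simulated value is therefore not what a shared array alone would give here.

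The comparison of 6 h with 4 h asks which genes differ with the length of stimulation. At 6 h against 4 h, KRT19 was 11.0-fold higher (log2 3.46), MON1B, a subunit of an endosomal exchange factor, 7.60-fold, ZNF2 6.51-fold, NPY1R 6.35-fold and CX3CR1, the fractalkine receptor, 6.17-fold. SIRT6 (-3.62), IFI35 (-3.48), MARK2 (-2.76), NAT14 (-2.68) and SYTL1 (-2.50) were the 5 lowest of the ranking. Of 3447 genes in the stricter set 498 were at least 2-fold higher and 346 lower at 6 h; about the median difference of 0.40 these counts were 128 and 606, and the share of higher genes 17.4% in place of 59.0%. Levels on the unstimulated array correlated across genes at 0.97 with the 4 h and 0.99 with the 6 h array, and those of the treated arrays with each other at 0.96.

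At 6 h against 4 h, 4 of 31 lists in the wider set stood apart above their matched lists and 10 below. Ovarian epithelial markers (9 genes, 5 higher and 1 lower) had a median of 1.07 against 0.51, and growth factor genes (22, 7 higher and 1 lower) 0.81 against 0.29. The epithelial-mesenchymal list (19, 6 higher and 0 lower) had 0.81 against 0.36, and the liver list, added after seeing the data, 0.70 against 0.06 over 17 genes. NF-kB targets (27, 2 higher and 4 lower) had -0.02 against 0.44 and immediate early genes (28, 1 higher and 6 lower) 0.02 against 0.59. Feedback genes of the ERK pathway (17, 3 higher and 6 lower) had -0.20 against 0.45, and cholesterol synthesis genes (24, 3 higher and 2 lower) 0.18 against 0.66. Ribosomal protein genes (60, 0 higher and 7 lower) had 0.31 against 0.71, oxidative phosphorylation genes (54, 2 higher and 10 lower) 0.27 against 0.68, and hypoxia and glycolysis genes (32, 7 higher and 6 lower) 0.13 against 0.65. The unfolded protein and ATF4 list (30, 4 higher and 6 lower) had 0.23 against 0.64, heat shock genes (20, 4 higher and 4 lower) 0.04 against 0.55, and housekeeping genes (19, 1 higher and 2 lower) 0.36 against 0.67. In the stricter set 15 lists could be tested and 5 stood apart: the epithelial-mesenchymal, ovarian epithelial and liver lists above, and ribosomal and housekeeping genes below. There NF-kB targets (7 genes) had 0.56 against 0.48, growth factor genes (10) 0.58 against 0.41, hypoxia and glycolysis genes (7) 0.65 against 0.60 and oxidative phosphorylation genes (9) 0.55 against 0.63, at percentiles 63.0, 76.8, 59.9 and 28.7. With the length trend removed from the wider set, NF-kB targets (percentile 3.04), ERK feedback (4.11), growth factor (93.9) and ovarian epithelial genes (97.3) did not stand apart. The median of all genes was itself 0.41 in the wider set, so the sign of a wider-set median between 0 and 0.41 rests on the scaling. Medians of the 4 lists that stood apart above exceeded 0.41, and those of NF-kB targets and ERK feedback genes lay below 0. Lists were not placed with another scaling for this comparison.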

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

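No test in this part was run, and the differences between the 2 times below were not tested, since each time has 1 array. KRT19, a keratin of simple epithelia, lay on opposite sides of the unstimulated array at the 2 times, at -1.56 at 4 h and 1.90 at 6 h. APOA2, an apolipoprotein, was at -1.02 at 4 h and 1.34 at 6 h. NPY1R, a neuropeptide Y receptor, was at -1.34 and 1.33. CX3CR1, the fractalkine receptor, was at -1.49 and 1.13. These 4 genes of the stricter set were at least 2-fold lower at 4 h and higher at 6 h, where independent lists would share 3.88, and 0 genes went the other way against 3.84. Relative to the 4 h median of all genes, KRT19 stood at -1.14, CX3CR1 at -1.08, NPY1R at -0.92 and APOA2 at -0.61, so that 2 of the 4 were less than 2-fold lower.

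Probes without a gene name were not used in any comparison. Of 2861 such probes in the stricter set at 4 h, 122 were at least 2-fold higher and 631 lower than on the unstimulated array. At 6 h, 37 of 3299 were higher and 28 lower. Against the 4 h array, 826 of 3305 were at least 2-fold higher at 6 h and 162 lower.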

How the results depend on the processing

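Counts below are genes at least 2-fold higher and lower, beside 236 and 348 at 4 h, 45 and 82 at 6 h, 498 and 346 for 6 h against 4 h, and a correlation of 0.158 between the differences at both times. Normexp, the brightest eligible probe, the removal of a gene-length trend, and the wider set with quantile or median scaling were chosen after seeing the data; the other alternatives were planned. A 1.5-fold threshold gave 420 and 1109 at 4 h, 210 and 265 at 6 h, and 1328 and 615 for 6 h against 4 h, by its construction. Without the filter on dim probes more genes entered: 442 were higher at 4 h, 82 higher at 6 h and 542 lower at 6 h against 4 h, with a correlation of 0.290. Keeping only the brighter part of the genes left 52 and 186 at 4 h, 16 and 39 at 6 h, and 305 and 93 for 6 h against 4 h, with a correlation of 0.208. The wider set holds more genes and gave 1412 and 1497, 106 and 143, and 2321 and 1736, with a correlation of -0.088. With quantile normalization it gave 1461 and 922, 94 and 156, 1359 and 1870, a correlation of -0.077 and an NF-kB target median at 4 h of 0.194, then above its matched lists. With median scaling it gave 1143 and 2433, 80 and 200, 2685 and 1604, and -0.088. In the stricter set, median scaling gave 569 lower genes at 4 h, quantile normalization a correlation of 0.115, and cyclic loess 29 higher at 6 h, and 321 higher and 424 lower at 6 h against 4 h, where higher genes made up 43.1% in place of 59.0%. The authors' value table gave 624 lower at 4 h and 148 lower at 6 h. The median over a gene's probes gave 382 higher at 4 h and 548 lower at 6 h against 4 h, and the brightest eligible probe 372 higher at 4 h. Normexp gave 99 and 176 at 4 h, 22 higher at 6 h, 216 and 132 for 6 h against 4 h, and a correlation of 0.223; of the 236 and 348 genes at 4 h it kept 90 and 151. Except where the number of genes, the threshold or the raised dim values show it, the cause was not tested.

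Scaling by the array median moved the share of higher among 2-fold genes from 40.4% to 23.9% at 4 h and from 35.4% to 22.9% at 6 h. At 6 h it was 20.3% with cyclic loess and 19.6% with the authors' table. Cyclic loess left it at 40.6% at 4 h. The 89 differences of ranked and fixed-set genes in the stricter set were followed across settings. A difference of at least 2-fold there fell under 2-fold with its direction kept in 35 pairs with a setting, and reversed in 0. In the other 986 pairs the difference stayed at least 2-fold in its direction, or had been under 2-fold in the stricter set. For the latter a turn of sign was not followed. Genes named only as list members were not followed here. IL17A target and stem cell lists had 4 members in the stricter set at 4 h, too few to be tested there. Where they could be tested there, the IL17A target, NF-kB and stem cell lists did not stand apart. Where both the stricter set and the alternative had at least 5 members, they again did not in 48 of 49 list and setting pairs. With no list apart to begin with, this says little about stability, and the sign of the median turned in 20 of these pairs. The IL17A target median at 4 h ran from -0.57 to 0.39 over the alternatives. The -0.57 came without the filter on dim probes, where a dim value was raised to its array's lowest level well above background. It is the gap between those levels on the unstimulated and 4 h arrays (-4.53 and -5.10) and measures no response. NF-kB and stem cell medians were -0.57 there as well. The next lowest IL17A target median was -0.11, with the median over a gene's probes. No paired analysis was possible because the groups share only replicate number 1, with 1 array each. Not run were normexp on the mean signal, a column not used here, and spike-in scaling, since 2, 1 and 9 of 320 spike-in spots were well above background. Signal over background limits the dim genes: the lowest signal called well above background was 48.1 on the unstimulated, 58.3 on the 4 h and 30.4 on the 6 h array.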

Other observations

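The tests of explanations in this part were set before their results were seen, except that the list of liver transcripts was drawn up after the plasma protein genes had been noticed. The genes EXOC3L1, JPH3, BOK, RBP4 and HAMP were chosen after their values were seen. ID3, an inhibitor of basic helix-loop-helix factors, was higher by 1.80 at 4 h and at -1.52 at 6 h, and DDIT3, a stress-induced transcription factor, at 2.30 and -1.14. They are among 12 genes of the wider set at least 2-fold higher at 4 h and lower at 6 h, where independent lists would share 16.6. Interferon-stimulated genes (27 measured, 5 higher and 1 lower by 2-fold at 4 h) had a 4 h median of -0.21 against -0.45 in matched lists, percentile 92.9, with IFIT3 at 2.38 and ISG15 at 1.497. At 6 h their median was -0.01 against 0.04.

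Drug efflux transporters (11 measured) had a median of 0.03 against -0.31 at 4 h and -0.13 against 0.02 at 6 h, and did not stand apart. Among them ABCA3, a lipid transporter, was at 2.51 at 4 h and -0.07 at 6 h, and ABCA2 at 1.56 and 0.92. TGF-beta and BMP targets (13 measured) had -0.28 against -0.27 at 4 h and -0.09 against 0.03 at 6 h, with the inhibitory SMAD7 at -1.07 and -0.98. Markers of fibroblasts (14 measured, -0.54 against -0.39 at 4 h) and of endothelial cells (6 measured, -0.42 against -0.05) did not stand apart. The endothelial marker KDR alone was far from its list median, at -4.14 at 4 h. Its probe carried the outlier flag on the unstimulated array, the 4 h array or both. Among single genes, EXOC3L1 was higher by 4.23 at 6 h with the outlier flag on that array, JPH3, a junction protein of excitable cells, was at -3.58 and -3.99 with the flag on the unstimulated array, and BOK, a BCL2 family member, was at -3.02 at 6 h.

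The 4 h array stood apart from both others, with a spread of differences across genes 2.30 times that at 6 h in the wider set. A response that varies with brightness is argued against as the whole cause, because the ratio was 2.25 after quantile normalization (95% bootstrap interval over genes 2.18 to 2.32). A trend with gene length is argued against in the same way: longer genes were lower at 4 h (Spearman correlation -0.183 across genes), but removing the trend left a ratio of 2.21 (2.15 to 2.28). Noise of single probes cannot be told apart from a difference between samples, since the 4 h differences of 2 probes of one gene correlated at 0.306 (0.275 to 0.337, 3400 genes), above the 0.113 at 6 h but between the bounds set for either answer; in the wider set 935 of 1710 genes with several probes and a 2-fold probe had probes of opposite sign at 4 h. IL17A at 4 h, a difference between cultures and a difference in RNA or labelling all remain open with 1 array per group.

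SERPINA1, A2M, TF, RBP4 (-2.27 at 4 h and -1.64 at 6 h) and HAMP (-1.35 and -1.08), genes for plasma proteins, were lower on both treated arrays, whereas others such as APOA2 (1.34) and APOH (0.39) were higher at 6 h, and 1 of the 16 listed liver transcripts measured on all 3 arrays was 2-fold lower there. RNA from liver cells in the unstimulated sample is argued against by the 6 h array, where these 16 had a median of -0.0964 (lower 95% bound -0.122) and albumin (ALB) lay at -0.12; with SERPINA1, A2M, TF, AHSG, RBP4 and APOA2 added the median over 22 was -0.11. At 4 h, by contrast, the same 16 had a median of -0.78 against -0.14 in matched lists (percentile 0.11), with ALB at -1.28. A bright patch on the unstimulated array is argued against by the 296 neighbouring spots of the 28 genes lower at both times, whose median at 6 h was -0.00244 (-0.0648 to 0.0634). As a hypothesis, these few genes may be lower under IL17A at both times, but a feature of the 1 unstimulated culture would look the same and remains open.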
